A study of Bacillus subtilis subsp. subtilis str. 168 with 12 samples.

How the data were processed

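Total RNA was taken from log-phase cultures of the 2 strains before rifampicin and 2 and 5 min after it. Per the labels' protocols, cells were harvested on frozen sodium azide, RNA was extracted with acid phenol and treated with DNase, and libraries were made with a stranded total RNA ligation kit that depletes ribosomal RNA. The authors deposited raw counts of read pairs per gene name, with 1 column per library and no normalization. Per the file headers, read pairs were counted with featureCounts 2.0.3 over CDS and exon features of an annotation of NC_000964, grouped by gene name. Per the submitters' processing notes, reads were aligned with Bowtie2 2.5.1. The counting command in the file header sets no strand option, so reads of a gene and of its antisense partner, or of overlapping genes, cannot be told apart. Read pairs without molecular identifiers are not independent molecules, and the limits given for a count of 0 cover counting error only.

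The table has 4441 genes, all matched by name to the reference table of assembly ASM904v1. Positions are those in the deposited table, counted from 1. The rows include 30 of rRNA and 86 of tRNA, which come in near-identical copies whose reads the counting could split, so single rows of these classes are uncertain. A gene name covered segments over 10000 bases apart for 7 names, none of which is discussed. Among the genes named in the text, the larger overlaps with a neighbour are 141 bases between srfAB and comS, 65 between sigX and rsiX, and 29 between motA and motB, each on the same strand. The fixed rule for genes of strain construction names the alarmone synthetases and nahA, which the table lists as relP, relQ and yvcI. The table's names were not matched one by one to SasA and SasB.

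Libraries were grouped by strain and time from their labels, 2 per group, with totals of 18107308 to 25285898 counts. The series design text calls the replicates biological and says that cultures were sampled repeatedly. Replicates differed by far more than sampling noise (chi-square per degree of freedom from 51.5 to 145 over the 6 groups), so none was counted as a repeat. The strains were compared before rifampicin with the 4 libraries of 0 min alone (4215 genes). Changes after rifampicin, and their differences between the strains, came from 1 fit of the 6 group means of all 12 libraries (4244 genes). Both used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, the quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. Errors of log2 values are SE from these fits unless SD is named.

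Genes were named by a rule fixed before the data were examined, which takes the construction genes and the 15 largest rises and 15 largest falls per comparison among called genes with mean log2 CPM of at least 3 and no overlap of the libraries. The rule adds the 10 genes of smallest p where fewer than 5 passed, and up to 4 members of each list with the smallest p in the comparison described. Genes of unknown function and operon members after the third may be left out. The falls among protein-coding genes with at least 10 counts in each library compared were added after the data were seen. The 38 gene lists were also fixed beforehand, and 37 of them, those with more than 1 member measured, were tested with camera of limma 3.58.1 (preset correlation 0.01, then estimated) and with fry.

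Apparent half-lives came from the least-squares slope of log2 count over 0, 2 and 5 min per culture, with 0.5 added and counts divided by the summed counts of 5 stable RNAs: RNase P RNA (rnpB), tmRNA (ssrA), signal recognition particle RNA (scr) and both forms of 6S RNA. Protein-coding genes with at least 50 counts at 0 min in every culture were used. Medians were taken over the genes with a negative slope. Strains were compared by an exact permutation test of culture medians.

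The tests were checked on simulated counts drawn from the fitted means and the fitted trend of dispersion with abundance, with 99 or 100 tested genes changed 2-fold and 100 changed 4-fold. At 0 min 68% of 2-fold and 99% of 4-fold changes were called, with 10 false calls among 4194 genes. In the same way 8 false calls came up among 4223 genes for the strain difference at 2 min and 1 among 4221 at 5 min. These counts held no gene-to-gene spread around that trend and no effect shared by the libraries of a culture. The planted changes also loosen the adjustment compared with data where few genes differ. Tests of the real counts can therefore call fewer changes than these shares. For half-lives, the culture medians were recovered within 2.38% where the reference RNAs had counting error alone. Over 20 draws in which they also varied with a dispersion of 0.05 the median error was 8.62% and the largest 29.5%. Each reference varied on its own in these draws. In the data rnpB, ssrA and scr were low together in the 0 min library of KAE213 replicate 2. They made up 0.157%, 0.203% and 0.0713% of its counts, against 0.292%, 0.689% and 0.199% in replicate 1. The simulated errors can therefore understate those of the real half-lives.

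Alternatives covered DESeq2's size factors within edgeR, DESeq2 1.42.0, no filter, scaling to the stable RNAs, leaving out 122 rows of rRNA, tRNA and stable RNA, a test against a 1.5-fold change, each culture left out, the 0 min library of KAE213 replicate 2 left out under either scaling, the 5 min library of KAE213 replicate 1 left out under stable RNA scaling (alone and with the former), counts thinned to 0.5 of the depth, and blocks for the replicate number or the culture. Libraries with the same number within a strain come from the same culture by the design text, and their deviations from the group means correlated at 0.31 to 0.62 across genes. Numbers shared across the strains mark nothing that the labels name. Libraries of the same number in different strains nevertheless correlated at -0.207, 0.457 and 0.364 at 0, 2 and 5 min. The range within cultures thus does not by itself mark a shared culture. Paired values appear where they change a call and for the comparisons after rifampicin.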

Results

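RNA sequencing was used to compare 2 strains of Bacillus subtilis that cannot make the alarmones ppGpp and pppGpp, the nucleotides that accumulate when amino acids run out. KAE55 lacks the synthetases Rel, SasA and SasB. KAE213 lacks the same enzymes and also carries E49Q and E53Q in NahA, a Nudix hydrolase that makes pGpp from ppGpp and pppGpp. Cultures in S7 minimal medium were sampled in log phase (0 min) and again 2 and 5 min after rifampicin at 150 µg/mL, an antibiotic that blocks the start of transcription by RNA polymerase. Each strain had 2 cultures, which gave 12 libraries in 6 groups of 2. Library totals ran from 18107308 to 25285898 counted read pairs over 4441 genes. In a principal component analysis of log2 CPM (counts scaled to the library total), the first component held 84.5% of the variance and the second 6.11%.

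The genes of strain construction were examined first in every library. The 2 genes of small alarmone synthetases were at background: relP (chromosome positions 1237006 to 1237641 of NC_000964.3, plus strand) had 0 counts in all 12 libraries, and relQ (3949952 to 3950584, minus strand) had 0 to 4. A count of 0 allows up to 0.119 to 0.166 CPM at these depths, for counting error alone. The rel gene was not analysed here. NahA is encoded by yvcI (3572413 to 3572889, minus strand). This gene was transcribed in both strains, so its transcript level does not check the base changes that KAE213 carries.

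To find which transcripts differed between the strains during growth, KAE213 was compared with KAE55 at 0 min. The transcript with the smallest p was yvcI itself, at 77.0 ± 5.41 normalised CPM in KAE213 and 35.4 ± 5.19 in KAE55 (SD, n = 2 cultures per strain), a log2 ratio of 1.12 ± 0.17 (SE), or 2.18-fold. Adjoining genes of threonine synthesis, hom (homoserine dehydrogenase) and thrC (threonine synthase), had log2 ratios of 0.66 ± 0.17 and 0.60 ± 0.14, and serA of serine synthesis 0.40 ± 0.11. The whole list of threonine and lysine synthesis had a median of 0.061 (6 of 8 genes higher) and did not pass camera (adjusted p = 0.101, 0.802 with an estimated correlation). The transporter genes opuE (proline uptake), csbC and ywtG had log2 ratios of 0.63 ± 0.14, 0.64 ± 0.15 and 0.68 ± 0.16, and sunT, the exporter of the bacteriocin sublancin, 1.00 ± 0.24. None of these passed the threshold over all 4215 genes tested. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called, the smallest adjusted p was 0.990, and 92 genes had an unadjusted p under 0.05. DESeq2 called 1 gene, yvcI (adjusted p = 8.25e-04). Adjusted over the list alone, edgeR called yvcI in the list of genes around nahA, and hom and thrC in the list of threonine and lysine synthesis. The libraries of the strains did not overlap for 1179 genes (28.0%, where chance gives 1 in 3). The 95% interval of the log2 ratio lay within 1 of 0 for 82.1% of all genes and for 93.5% of the 3056 with a mean log2 CPM of at least 3. Without KAE213 replicate 1 the log2 ratio of sunT was 1.27. That fit rests on 1 KAE213 library, which stood apart in its RNA classes as described below.

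Groups of genes fixed before the data were examined gave small shifts in both directions at 0 min. Members of the SigB general stress regulon were higher in KAE213 for 19 of 21 genes (median log2 ratio 0.43), with katE (catalase) at 0.66 ± 0.21, ydaG at 0.70 ± 0.22 and bmrU at 0.86 ± 0.28. The SPbeta prophage was higher for 79 of 93 genes (median 0.30), for example yonA at 0.90 ± 0.27 and yomX at 0.77 ± 0.23. Medians were also positive for biofilm matrix genes (0.30, 18 of 20 higher), early sporulation and cannibalism (0.29, 17 of 20), branched-chain amino acid synthesis (0.28, 10 of 11), histidine synthesis (0.23, 5 of 7) and sulfur amino acids (0.18, 8 of 12). Examples were leuC at 0.66 ± 0.20 and leuB at 0.63 ± 0.19 of leucine synthesis, and sat at 0.51 ± 0.15 and metE at 0.71 ± 0.22 of sulfate assimilation and methionine synthesis. All 12 genes of de novo purine synthesis were lower in KAE213 (median -0.18), with purC at -0.39 ± 0.10 and purK at -0.29 ± 0.11. The other lists with negative medians among those that passed camera were the surfactin synthetase genes (-0.73, 0 of 4 higher), with srfAA at -0.74 ± 0.41 and srfAB at -0.79 ± 0.46, the PBSX prophage (-0.20, 1 of 30), with xkdU at -0.45 ± 0.22, nitrogen assimilation (-0.20, 2 of 11) and ribosomal proteins (-0.07, 15 of 54), with rplL at -0.76 ± 0.20 and rplX at -0.43 ± 0.14. No member of these lists passed the threshold, over all genes or adjusted over the list alone. These 12 of 37 lists passed limma's camera test with a preset inter-gene correlation of 0.01, with adjusted p from 5.69e-10 for SPbeta and 6.04e-07 for SigB to 0.0315 for histidine synthesis. With an estimated correlation 0 lists passed (smallest adjusted p = 0.802), and with limma's fry 0 passed (smallest adjusted p = 0.581). Camera with an estimated correlation passed 0 lists after rifampicin too, so missing it does not decide whether a list differs.

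The 0 min library of KAE213 replicate 2 stood apart in its RNA classes, with 0.437% of counts in 5 stable non-coding RNAs against 0.937% to 1.19% in the other 0 min libraries, and 0.525% in tRNA rows against 0.797% to 0.859%. Without it the medians were 0.059 for SPbeta, 0.17 for SigB, 0.13 for early sporulation, 0.44 for branched-chain amino acids, 0.35 for sulfur amino acids, -0.13 for ribosomal proteins, -0.61 for PBSX and -0.32 for surfactin synthetase. Without KAE213 replicate 1 they were 0.54 for SPbeta, 0.14 for branched-chain amino acids, 0.073 for sulfur amino acids, -0.32 for nitrogen assimilation, 0.12 for PBSX and -1.40 for surfactin synthetase. Without KAE55 replicate 1 they were 0.49 for SPbeta, 0.038 for biofilm matrix, 0.18 for branched-chain amino acids, -0.35 for PBSX and -1.19 for surfactin synthetase. Without KAE55 replicate 2 they were 0.18 for SPbeta, 0.67 for biofilm matrix, 0.16 for early sporulation, -0.0020 for PBSX and -0.0021 for surfactin synthetase. Histidine synthesis stayed between 0.23 and 0.33 and purine synthesis between -0.22 and -0.18 with any library left out.

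**Figure D1:**
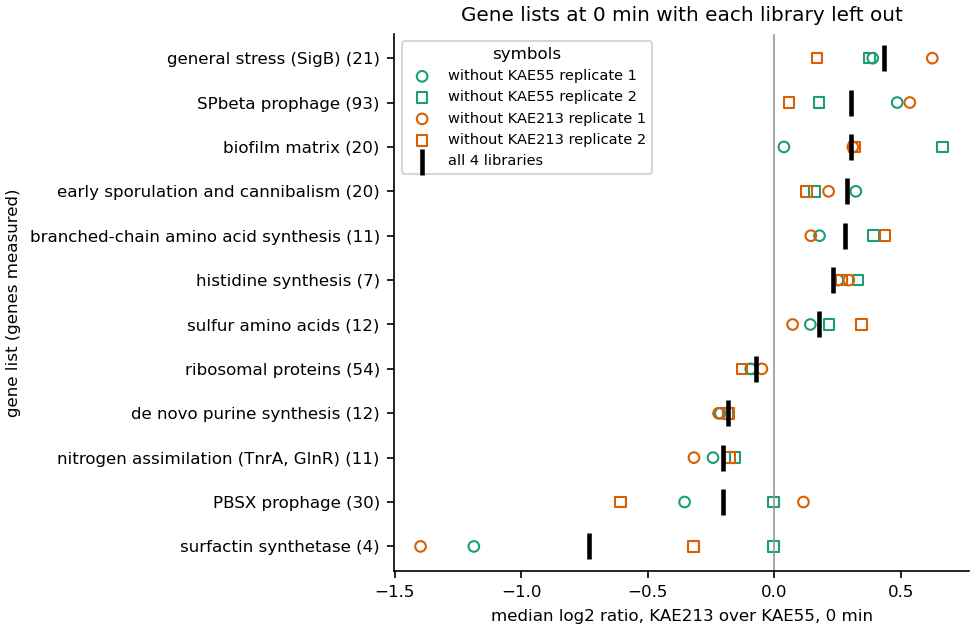
Median log2 ratio of KAE213 over KAE55 at 0 min (x axis) for the 12 gene lists that passed camera with the preset correlation (y axis, genes measured in parentheses). Black bars use all 4 libraries and open symbols leave out 1 library, and the purine synthesis symbols lie together between -0.22 and -0.18 while those of the surfactin synthetase genes run from -1.40 to -0.0021.

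Rifampicin was used to follow how transcripts decayed once no new ones were started. Many of the deepest falls were in tRNA rows. In KAE55 84 of 84 measured tRNA genes fell after 2 min and after 5 min, and in KAE213 83 and 82 did (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Their share of all counts went from 0.828% ± 0.0434 at 0 min to 0.0218% ± 0.00531 and 0.0136% ± 0.000575 in KAE55, and from 0.682% ± 0.223 to 0.0186% ± 0.000210 and 0.0169% ± 0.00162 in KAE213 (SD, n = 2 cultures per group). Most tRNA rows then held 3 counts or fewer (51 to 67 of 86 per library), so no fold is given for them. Counts per row do not tell mature tRNA from its precursors, so these falls are not read as decay of mature tRNA. All log2 changes were relative to the typical transcript, since the libraries were scaled by TMM. Scaled instead to the summed counts of the 5 stable RNAs, the median log2 change of all genes moved from -0.11 to -1.27 and from -0.15 to -1.97 after 2 and 5 min in KAE55, and from -0.07 to -2.15 and from -0.17 to -3.41 in KAE213. The KAE213 values on that scale rest in part on the 0 min library of replicate 2, where the stable RNA share went from 0.437% to 1.49% by 2 min, against 1.19% to 1.61% in replicate 1. Without that library, a check chosen after the data were seen, the KAE213 medians were -1.25 and -2.51. The 5 min library of KAE213 replicate 1 also stood apart, with 2.30% of counts in tmRNA against 0.890% to 1.25% in the other 5 min libraries. Without it the KAE213 median at 5 min was -3.03, and without both libraries -2.13, where the 0 and 5 min values come from different cultures. A relative rise can therefore go with a fall in amount. Genes named below whose direction turned on the stable RNA scale are named as such, and list medians on that scale are given for most of the lists described.

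After 2 min in KAE55, transcripts of surfactin synthetase and of the promoter-distal genes of the fla/che operon (flagellar basal body and chemotaxis) rose relative to the typical transcript. The log2 change was 2.78 ± 0.52 for srfAC, 2.66 ± 0.63 for srfAD, 2.32 ± 0.19 for cheW, 2.27 ± 0.21 for cheA and 2.23 ± 0.23 for flhG. The 15 deepest falls of protein-coding genes with at least 10 counts in each library compared included tagA and tagB of wall teichoic acid synthesis at -5.90 ± 0.39 and -5.07 ± 0.25, sigX (an envelope stress sigma factor) at -4.96 ± 0.35, ftsE at -4.85 ± 0.24, rodA (cell shape) at -4.17 ± 0.21 and the endopeptidase gene cwlO at -4.00 ± 0.19. These genes are a selection made after their values were seen and not the deepest in order, because most of the deepest falls by the fixed rule were tRNA rows and genes left with few counts. The same holds for the falls named below. In the fla/che operon 26 of 32 genes rose and 2 fell (27 and 2 adjusted over the list alone), and among ribosomal proteins 39 of 54 rose and 3 fell (40 and 4). In the PBSX prophage 23 of 30 rose and 0 fell (23 and 0). In glycolysis 10 of 11 rose and 1 fell, in the TCA cycle 10 of 12 rose and 0 fell, and among translation factors 8 of 11 rose and 3 fell, each the same adjusted over the list alone. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, 963 genes were higher and 1306 lower of 4244 tested. On the stable RNA scale 3 were higher and 1646 lower, and cheW, cheA and flhG no longer passed. In fla/che 0 genes rose and 3 fell there, and among ribosomal proteins 0 rose and 5 fell. The list median there stayed positive for surfactin synthetase, fla/che (0.63), PBSX (0.11) and glycolysis (0.03) and turned to -0.30 for ribosomal proteins, -0.28 for the TCA cycle, -0.22 for translation factors and -0.59 for SPbeta (35 of 109 genes higher and 15 lower on the TMM scale). Fewer genes were called with either KAE55 culture left out, which leaves 1 KAE55 library per time. Without KAE55 replicate 1 srfAD and flgB no longer passed. The log2 change was then 2.56 for srfAD, near the 2.66 with all libraries, and -0.59 for flgB.

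Within long operons the change after 2 min in KAE55 followed the distance from the first gene. In the pur operon of purine synthesis the first gene, purE, fell by 1.68 ± 0.28 and the last, purD, rose by 1.62 ± 0.13. In the pyr operon of pyrimidine synthesis pyrR fell by 3.17 ± 0.23 and pyrE rose by 1.46 ± 0.16, and in the fla/che operon flgB fell by 0.90 ± 0.23. Of the 12 purine genes 6 rose and 3 fell (6 and 4 adjusted over the list alone), and of the 10 pyrimidine genes 6 rose and 2 fell (6 and 2). On the stable RNA scale 0 purine genes rose and 4 fell, with the list median turning from 0.32 to -0.85, and 0 pyrimidine genes rose and 2 fell, with the median turning from 0.97 to -0.20. There purD (0.45) and pyrE (0.30) no longer passed. Spearman's correlation of position and change, across genes that are not independent replicates, was 0.834 to 0.954 over the 32 fla/che genes in the 4 cultures of both strains. It was 0.986 to 1 over 12 pur genes and 0.952 to 0.988 over 10 pyr genes. Over 28 PBSX genes from xkdB to xlyA, which need not share 1 transcript, it was 0.741 to 0.873.

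**Figure D2:**
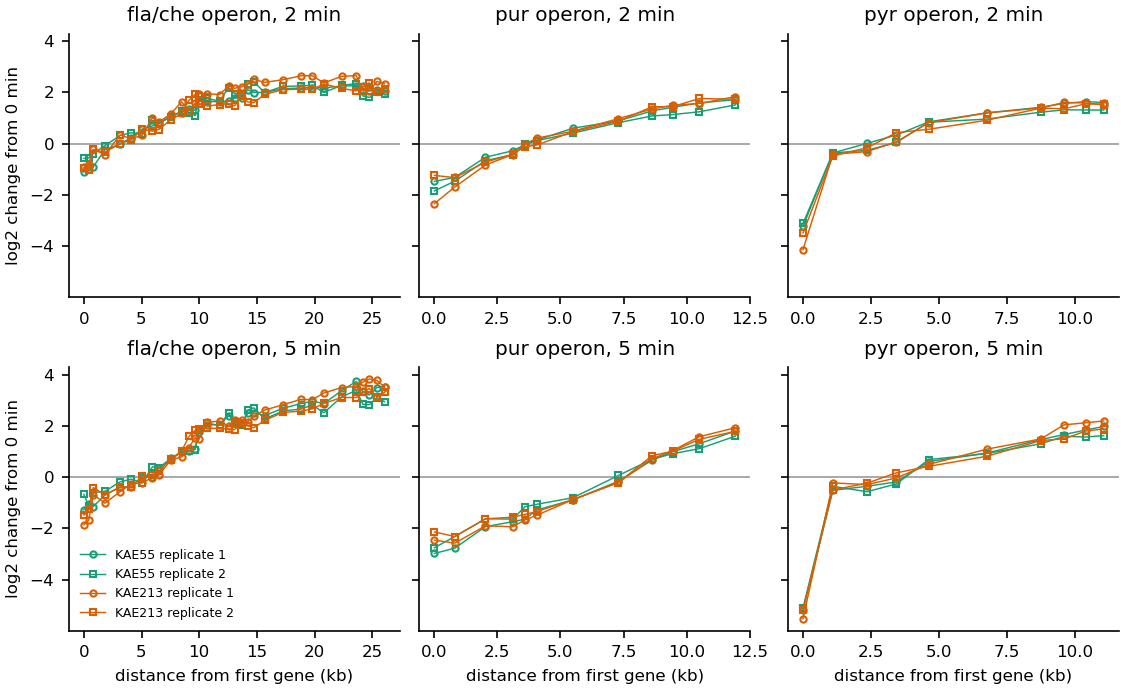
Log2 change from 0 min after 2 min (top) and 5 min (bottom) of rifampicin (y axis) against distance from the first gene in kb (x axis) for the genes of the fla/che, pur and pyr operons, with 1 line per culture. Changes are relative to the typical transcript, and in each culture the first genes lie below 0 and the last ones above it.

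After 5 min in KAE55 the relative rises were led again by surfactin and motility genes, with srfAC at 3.89 ± 0.54, srfAD at 3.85 ± 0.66, cheW at 3.59 ± 0.20, the motility sigma factor gene sigD at 3.32 ± 0.26 and swrB at 3.28 ± 0.22. The 15 deepest falls of protein-coding genes with at least 10 counts in each library compared included -6.86 ± 0.43 for tagA, -5.39 ± 0.26 for ftsE, -5.28 ± 0.29 for bofA, -5.20 ± 0.26 for pyrR and -4.79 ± 0.29 for rnpA, the protein part of RNase P. Of 54 ribosomal protein genes 35 rose and 5 fell, with rpsK at 2.36 ± 0.16 and rpsM at 2.60 ± 0.18. In glycolysis 10 of 11 rose, with eno (enolase) at 2.25 ± 0.18 and gapA (glyceraldehyde 3-phosphate dehydrogenase) at 1.83 ± 0.18, which turned to -0.018 on the stable RNA scale, while cggR, the repressor gene ahead of gapA in the same operon, was at -1.96 ± 0.14. In the TCA cycle 10 of 12 rose and 0 fell, with mdh at 2.21 ± 0.17, icd at 2.01 ± 0.16 and citB at 1.60 ± 0.15, the last turning to -0.21 on the stable RNA scale. Prophage genes also rose, 24 of 30 in PBSX with 0 falling (xlyA at 2.46 ± 0.29 and xkdM at 1.97 ± 0.25) and 61 of 109 in SPbeta with 19 falling (yonB at 2.57 ± 0.16 and yopC at -4.83 ± 0.29). These list counts were the same adjusted over the list alone. In the fla/che operon 24 of 32 rose and 4 fell, adjusted over the list alone too. In the pur operon purK was at -2.52 ± 0.18 and purD at 1.70 ± 0.13, and in the pyr operon pyrE at 1.80 ± 0.17, where purD turned to -0.15 and pyrE to -0.043 on the stable RNA scale. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, 1297 genes were higher and 1617 lower, and on the stable RNA scale 8 and 2664. On that scale rpsK (0.53), rpsM (0.72), eno (0.40), mdh (0.40), icd (0.20), xlyA (0.61), xkdM (0.16) and yonB (0.75) kept their sign but no longer passed. In fla/che 4 genes rose and 9 fell there, and among ribosomal proteins 0 rose and 21 fell. The list medians on the stable RNA scale were 1.66 for surfactin synthetase, 0.19 for fla/che, 0.07 for PBSX, -0.04 for glycolysis, -0.18 for SPbeta, -0.26 for the TCA cycle and -0.69 for ribosomal proteins. They were -1.05 for pyrimidine synthesis and -2.84 for de novo purine synthesis.

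In KAE213 surfactin, flagellar and chemotaxis genes also led the relative rises after 2 min, with srfAC at 2.92 ± 0.52, srfAD at 2.89 ± 0.63, flhG at 2.42 ± 0.23, cheA at 2.42 ± 0.21 and cheW at 2.37 ± 0.19. The 15 deepest falls of protein-coding genes with at least 10 counts in each library compared included -5.99 ± 0.40 for tagA, -5.65 ± 0.25 for ftsE, -5.22 ± 0.25 for tagB, -4.58 ± 0.34 for sigX and -4.35 ± 0.21 for rodA. In the fla/che operon 26 of 32 genes rose and 3 fell (26 and 3 adjusted over the list alone), and among ribosomal proteins 42 of 54 rose and 2 fell (43 and 2). In PBSX 23 of 30 rose and 0 fell (24 and 0), in the TCA cycle 11 of 12 rose and 0 fell (11 and 0), and in glycolysis 10 of 11 rose and 1 fell (10 and 1). In the pur and pyr operons purE fell by 1.79 ± 0.28 and pyrR by 3.78 ± 0.24, while purD was at 1.79 ± 0.13 and pyrE at 1.53 ± 0.16, which turned to -0.31 and -0.53 on the stable RNA scale. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, 1148 genes were higher and 1364 lower, against 0 and 3188 on the stable RNA scale (10 and 1963 without the 0 min library of replicate 2). On that scale with all libraries srfAC (0.97), srfAD (1.06), flhG (0.32), cheA (0.32) and cheW (0.21) kept their sign but did not pass. In fla/che 0 genes rose and 9 fell there, and among ribosomal proteins 0 rose and 27 fell. The list medians there were 0.89 for surfactin synthetase, -0.23 for fla/che, -0.62 for PBSX, -0.74 for glycolysis, -1.01 for the TCA cycle, -1.10 for ribosomal proteins and -1.37 for SPbeta. Without that library purD (0.61) and pyrE (0.29) did not turn, and the list medians were 1.11, 0.59, 0.83, 0.029, -0.18, -0.22 and -0.22. The genes called in both strains numbered 918 higher and 1208 lower, where independent lists would share 260 and 420, and 0 were called in opposite directions.

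After 5 min in KAE213 examples of relative rises were srfAD at 4.65 ± 0.68, srfAC at 4.32 ± 0.55, sigD at 3.49 ± 0.26, swrB at 3.44 ± 0.22 and cheW at 3.33 ± 0.19, with cheW turning to -0.026 on the stable RNA scale. The 15 deepest falls of protein-coding genes with at least 10 counts in each library compared included -5.43 ± 0.26 for ftsE, -5.39 ± 0.26 for pyrR, -5.29 ± 0.26 for tagB, -4.70 ± 0.27 for cymR (repressor of cysteine metabolism) and -4.59 ± 0.20 for tmk (thymidylate kinase). In the fla/che operon 23 of 32 genes rose and 4 fell, and among ribosomal proteins 37 of 54 rose and 4 fell. In PBSX 27 of 30 rose and 1 fell, in glycolysis 10 of 11 rose and 1 fell and in the TCA cycle 11 of 12 rose and 0 fell. Each count was the same adjusted over the list alone. The example genes rpsK (2.61 ± 0.16), eno (2.40 ± 0.18), mdh (2.22 ± 0.17) and xkdM (2.48 ± 0.25) turned to -0.73, -0.92, -1.13 and -0.89 on the stable RNA scale. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, 1362 genes were higher and 1660 lower, against 1 and 3917 on the stable RNA scale (3 and 3300 without the 0 min library of replicate 2). On that scale with all libraries srfAC (1.04), sigD (0.13) and swrB (0.16) kept their sign but did not pass. In fla/che 0 genes rose and 20 fell there, and among ribosomal proteins 0 rose and 47 fell. The list medians there were 0.65 for surfactin synthetase, -1.07 for PBSX, -1.27 for fla/che, -1.32 for glycolysis, -1.46 for the TCA cycle, -1.99 for ribosomal proteins and -1.84 for SPbeta. Without that library eno (-0.091) and mdh (-0.11) still turned while cheW (1.09), rpsK (0.19) and xkdM (0.47) did not. These medians were then 0.98, 0.43, -0.37, -0.53, -0.63, -1.19 and -0.51. Without the 5 min library of replicate 1 as well they were 0.67, 0.89, -0.10, -0.33, -0.45, -0.72 and -0.11, and eno (0.071) and mdh (0.13) did not turn. Both strains called 1177 genes higher and 1487 lower, where independent lists would share 416 and 632. The log2 changes of the strains had a Pearson correlation across genes, which are not independent replicates, of 0.938. Over the 4 comparisons with 0 min, camera with the preset correlation called 8, 6, 6 and 7 of 37 lists (2 and 5 min in KAE55, then in KAE213). All 4 sets included fla/che, ribosomal proteins, PBSX, SPbeta, glycolysis and the TCA cycle, each toward higher relative to the typical transcript. With an estimated correlation 0 lists passed, with smallest adjusted p of 0.951, 0.907, 0.887 and 0.858. That version thus missed glycolysis, where 10 of 11 genes rose and 1 fell, so missing it does not decide whether a list changed.

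To test whether the NahA substitutions changed the relative stability of any transcript, the change after rifampicin was compared between the strains. Around nahA the changes by 5 min were more negative in KAE213, with differences in log2 change of -0.76 ± 0.29 for yvcI, -0.69 ± 0.21 for yvcJ, -0.54 ± 0.18 for mgfK (also yvcK) and -0.52 ± 0.18 for whiA, a regulator of cell division, and of -0.07 ± 0.19 for trxB (thioredoxin reductase) on the upstream side. The yvcI transcript itself changed by -1.13 ± 0.21 in KAE55 and -1.89 ± 0.21 in KAE213. This difference shares the 0 min libraries with the higher level of yvcI in KAE213 at 0 min. As CPM of the library total, without TMM scaling, yvcI went from 31.7 and 38.2 at 0 min to 7.01 and 8.04 at 5 min in KAE55. In KAE213 it went from 81.6 and 74.2 to 7.19 and 11.3. These CPM are not on the TMM scale of the log2 changes, so the 2 measures do not compare directly. Among the 10 genes of smallest p were speE (spermidine synthase) at -0.69 ± 0.22, ftsE at -0.80 ± 0.32, clsA (cardiolipin synthase) at -0.50 ± 0.19 and alkA (DNA glycosylase) at -0.77 ± 0.29 after 2 min. After 5 min they included poxB (pyruvate oxidase) at 1.01 ± 0.29, fadH at 1.18 ± 0.35, dynA (dynamin-like protein) at -0.87 ± 0.28 and dutA (dUTPase) at -0.97 ± 0.31. The PBSX members with the smallest p after 5 min were xkdH at 1.01 ± 0.43 and xkdU at 0.92 ± 0.41. On the stable RNA scale poxB, fadH, xkdH and xkdU turned negative (-0.44, -0.26, -0.51 and -0.61), but not without the 0 min library of KAE213 replicate 2 (0.30, 0.36, 0.52 and 0.52). None passed the threshold over all 4244 genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called at 2 min (53 at unadjusted p under 0.05, smallest adjusted p = 1.000) and 0 at 5 min (176, smallest adjusted p = 0.903), and DESeq2 called 0 at both times (smallest adjusted p = 0.252 at 5 min). That edgeR fit does not pair the libraries of a culture. With the culture as a block edgeR also called 0 at both times, and the smallest adjusted p at 5 min was 0.139. Adjusted over the list alone, 4 of the 7 genes around nahA passed at 5 min. The 95% interval of the unpaired fit lay within 1 of 0 for 51.9% of genes at 2 min and 43.4% at 5 min. In simulated counts 26.3% of 2-fold and 84% of 4-fold differences were called at 2 min, and 24.2% and 73% at 5 min. Those counts lacked gene-to-gene spread in dispersion and effects of the culture, so the real test can call fewer.

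Among the gene lists camera called 1 at 2 min and 2 at 5 min. Ribosomal proteins had a median strain difference of 0.12 at 2 min (camera adjusted p = 0.0209), the 7 genes around nahA -0.54 at 5 min (4.36e-05) and the PBSX prophage 0.35 at 5 min (0.0350). With an estimated correlation the smallest adjusted p was 0.983 at 2 min and 0.631 at 5 min, the latter for the genes around nahA. That version also passed 0 lists in the comparisons with 0 min, so missing it does not decide this. Fry called 0 lists, with smallest adjusted p of 1.000 and 0.0596. On the stable RNA scale, where the median of all genes moved from 0.04 to -0.88 at 2 min and from 0.02 to -1.41 at 5 min, the list medians were -0.82 for ribosomal proteins, -2.02 for the genes around nahA and -1.19 for PBSX. Without the 0 min library of KAE213 replicate 2 that scale gave medians of 0.0085 and -0.52 for all genes at 2 and 5 min, 0.15 for ribosomal proteins, -1.04 for the genes around nahA and 0.31 for PBSX. Without the 5 min library of KAE213 replicate 1 as well, the 5 min medians were -0.16 for all genes, -0.67 for the genes around nahA and 0.86 for PBSX.

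**Figure D3:**
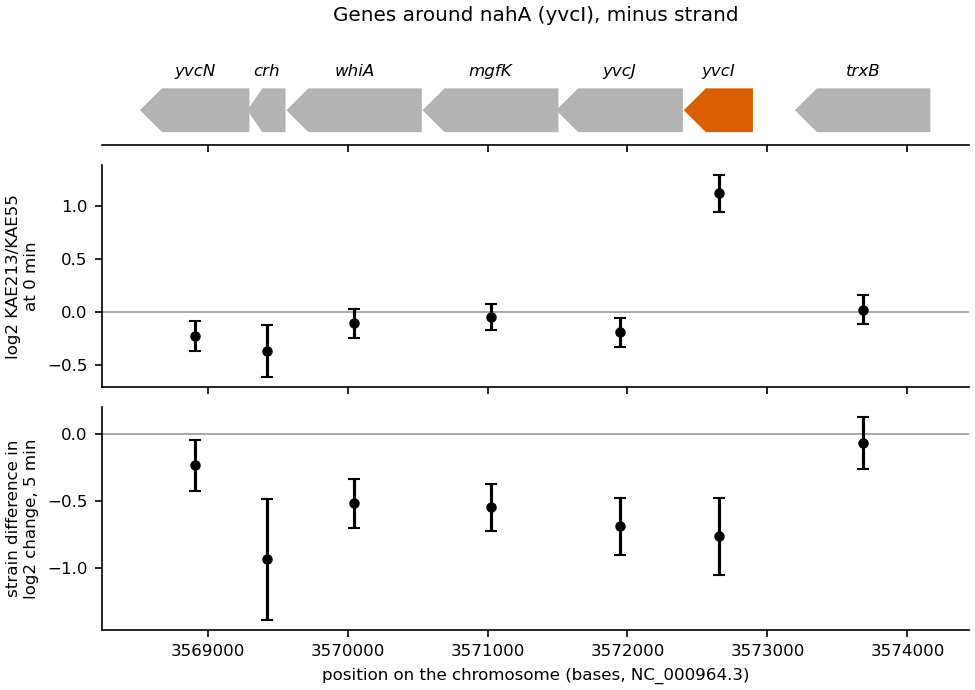
Genes around nahA (yvcI) to scale on the chromosome in bases (x axis), with the log2 ratio of KAE213 over KAE55 at 0 min (middle) and the strain difference in log2 change after 5 min of rifampicin (bottom), points with SE bars from edgeR. At 0 min yvcI stands at 1.12 and its 6 neighbours between -0.37 and 0.02, and at 5 min the 7 genes have a median of -0.54 on the TMM scale.

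To compare mRNA stability between the strains, an apparent half-life was computed per gene and culture from the fall of its count against the 5 stable RNAs. Of 3506 protein-coding genes 3383 and 3044 fell in the KAE55 cultures and 3481 and 3503 in the KAE213 cultures, and the others had no half-life. The median over the genes that fell was 2.00 and 2.90 min in the KAE55 cultures and 1.64 and 1.45 min in the KAE213 cultures, or 2.45 ± 0.637 and 1.55 ± 0.130 min (SD, n = 2 cultures per strain). The half-life of the median slope over all 3506 genes was 2.06 and 3.43 min in KAE55 and 1.65 and 1.45 min in KAE213. List medians were also taken over the genes that fell. Transcripts of de novo purine synthesis had medians of 1.74 ± 0.388 min in KAE55 and 1.16 ± 0.0707 min in KAE213, and the genes around nahA 2.48 ± 0.789 and 1.27 ± 0.122 min. Ribosomal proteins had 4.14 ± 0.413 and 2.96 ± 0.791 min, the TCA cycle 10.2 ± 1.82 and 4.24 ± 1.65 min, and glycolysis 14.9 ± 5.67 and 4.79 ± 2.27 min. The fla/che operon had 3.10 ± 0.363 and 3.19 ± 0.212 min. SPbeta had 2.34 ± 0.30 and 2.73 ± 0.416 min, and surfactin synthetase 3.18 ± 1.31 and 7.81 ± 8.25 min. Genes that did not fall in at least 1 culture numbered 1 of 12 for purine synthesis, 0 of 7 around nahA, 22 of 52 for ribosomal proteins, 6 of 12 for the TCA cycle, 7 of 11 for glycolysis, 19 of 32 for fla/che, 25 of 46 for SPbeta and 3 of 4 for surfactin synthetase. The list medians can therefore rest on different genes in each culture and do not order the strains. On the stable RNA scale the median strain difference in the 2 min change was -0.94 for SPbeta, -0.67 for surfactin synthetase and -0.80 for fla/che. Without the 0 min library of KAE213 replicate 2 these were 0.20, -0.39 and 0.012. The difference of -0.902 min between the strains' medians over all falling genes had an exact two-sided permutation p of 0.333 over 6 groupings, the smallest that 2 against 2 cultures can give, so this test could not pass. Leaving out KAE55 replicate 2 brought the difference to -0.453 min, and leaving out KAE55 replicate 1 to -1.35 min. With the 2 and 5 min libraries alone the strains overlapped, at 3.03 and 4.56 min in KAE55 and 1.89 and 3.05 min in KAE213.

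**Figure D4:**
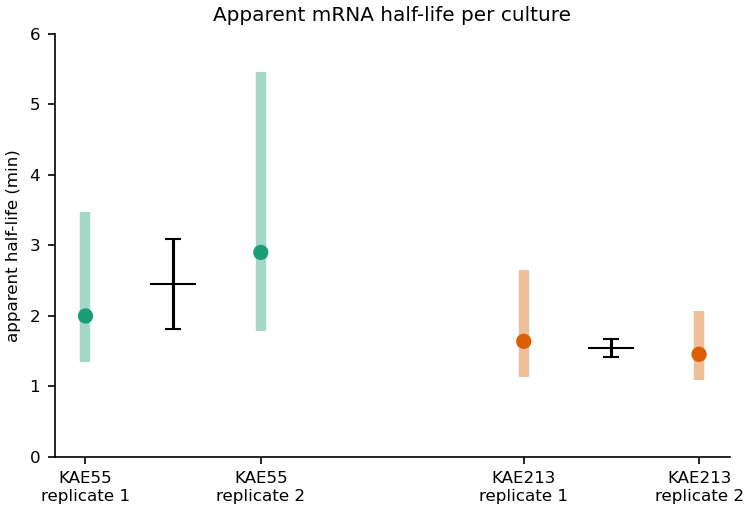
Apparent mRNA half-life in min (y axis) for the 4 cultures (x axis), with points for the median over the genes that fell (3044 to 3503 of 3506), shaded bars for their interquartile range, and black lines for the strain mean with SD. The medians are 2.00 and 2.90 min in KAE55 and 1.64 and 1.45 min in KAE213.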

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

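The test of the neighbours of yvcI at 0 min was chosen only after the result was seen. The differences between strains in these lists come from camera with the preset correlation, and none passed with an estimated one. The latter version takes the correlation from groups of 2 libraries and passed 0 lists in each comparison, also after rifampicin. Missing it therefore does not decide whether a list differs.

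Around nahA, yvcI stood higher in KAE213 at 0 min (log2 ratio 1.12, edgeR adjusted p = 0.990) and there was a median difference of -0.54 in the 5 min change of the 7 genes (camera adjusted p = 4.36e-05, 0.631 with an estimated correlation). Higher transcription of the whole operon is argued against, since the 6 neighbours had a median of -0.15 at 0 min, from -0.37 to 0.02. A single culture as the source of the 5 min shift is argued against too, as the median was at most -0.48 with any culture left out. Chance shifts of adjoining genes stay open: 190 of 4228 windows of 7 genes (4.49%) had a median as far from 0, and 31 of 2671 (1.16%) among genes with mean log2 CPM of at least 3. The second share is not like for like. The median of -0.54 includes crh, at most 4.07 CPM of the library total, which lies under that cut. For yvcI itself the difference in change shares the 0 min libraries with its 0 min difference. An effect of the nahA allele, or of its construction, on these transcripts stays open and was not tested.

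Ribosomal proteins had a median difference between the strains of 0.12 in the 2 min change (camera adjusted p = 0.0209, 0.983 with an estimated correlation). The PBSX prophage had a median difference of 0.35 in the 5 min change (camera adjusted p = 0.0350, 0.998 with an estimated correlation), and its lower level in KAE213 at 0 min (-0.20) shares the 0 min libraries with that difference. Branched-chain amino acid synthesis had medians of the log2 CPM change per culture of opposite sign at 2 min, -0.06 and -0.11 in KAE55 and 0.09 and 0.23 in KAE213, a gap of 0.245. In the edgeR fit the medians were 0.011 in KAE55 and 0.15 in KAE213, so the sign in KAE55 depends on the measure. This gap was not tested. The list test of the difference in change gave a camera adjusted p of 0.0903.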

How the results depend on the processing

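Most results kept direction and side of the threshold: of 1586 values of named genes under an alternative, 1507 did, 6 came past the threshold, 44 fell short of it (25 of them scaled to the stable RNAs, 8 so scaled without the 0 min library of KAE213 replicate 2, 5 without the 5 min library of KAE213 replicate 1, 4 without both, and srfAD and flgB in KAE55 at 2 min without KAE55 replicate 1) and 29 turned. No gene named at 0 min or in the strain differences passed in the main fit. For these, keeping the side of the threshold means missing it again. The crossed numbers at 0 min, the block by number at each time, the fits without the 0 min library of KAE213 replicate 2 or the 5 min library of KAE213 replicate 1, the scr and median-slope settings, and the thinned counts were chosen after seeing the data. The share that kept both was lower under scaling to the stable RNAs with all libraries, where 58 values did, 25 fell short and 16 of the 29 turned. Those that turned were in KAE55 at 5 min gapA (-0.018), citB (-0.21), pyrE (-0.043), purD (-0.15) and rph (-0.14). In KAE213 they were at 2 min purD (-0.31) and pyrE (-0.53) and at 5 min cheW (-0.026), rpsK (-0.73), eno (-0.92), mdh (-1.13) and xkdM (-0.89). In the strain difference at 5 min they were xkdH (-0.51), xkdU (-0.61), poxB (-0.44) and fadH (-0.26). So scaled without the 0 min library of KAE213 replicate 2, eno (-0.091) and mdh (-0.11) in KAE213 at 5 min still turned, but none of the strain differences did. So scaled without the 5 min library of KAE213 replicate 1, rpsK (-0.52), eno (-0.76), mdh (-0.89) and xkdM (-0.46) in KAE213 and xkdH (-0.13), xkdU (-0.21), poxB (-0.21) and fadH (-0.022) in the strain difference turned, and none did without both libraries. This scaling subtracts about the same amount from the log2 change of every gene, which is the cause. The other 3 were trxB, near 0 throughout: 0.043 in the strain difference at 5 min with counts thinned to 0.5 of the depth, and at 0 min -0.017 in the fit of all 12 libraries and from -0.016 to 0.060 with a library left out. The count of genes at 0 min was 1 with DESeq2 and moved with KAE213 replicate 1 left out. That fit leaves 1 KAE213 library, the one with a low share of stable RNA. The cause was not tested. Crossing the replicate numbers across strains, whose 0 min deviations correlated at -0.207 (0.457 at 2 min and 0.364 at 5 min), gave 4 calls against 0 with the numbers as labelled. The replicate block for culture gave 2506, 3055, 2710 and 3124 calls after rifampicin and changed no other call of a comparison. Paired by number at each time the strain differences also had 0. Leaving out a culture moved the KAE55 count at 2 min from 1187 (without KAE55 replicate 1) to 2433, with 1293 without KAE55 replicate 2. A group then has 1 library, which is assumed to vary like the other groups. Without the 0 min library of KAE213 replicate 2 the KAE213 counts were 2117 and 2719 (1973 and 3303 scaled to the stable RNAs), and the strain differences stayed at 0. Scaled to the stable RNAs at 5 min, the KAE213 count was 3327 without the 5 min library of replicate 1, with 0 strain differences. Without both it was 2982, with 1 strain difference, rocA. Then 0 and 5 min come from different cultures, and rocA was at 15.8 and 244 normalised CPM in the KAE213 replicates at 0 min. The 42 list calls over 7 comparisons became 0 with an estimated correlation and 88 with fry, which tests a list against no change and not against other genes. The half-life difference stayed negative in each setting, from -1.35 to -0.453 min with a culture left out, -1.08 with tmRNA alone, -0.872 with a minimum of 200 counts and -1.19 from the median slope. With every count thinned to 0.5 of the depth, the comparisons with 0 min called 97.9% to 99.3% as many genes with mean log2 CPM of at least 3, and 88.6% to 92.5% as many below it, where 1429 of 1557 genes were still tested. The strain comparisons stayed at 0 calls. In simulated counts of this size, without gene-to-gene spread in dispersion or effects of the culture, 26.3% and 24.2% of 2-fold and 84% and 73% of 4-fold strain differences in the change were called at 2 and 5 min.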

Other observations

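The tests of the nahA allele against half-life, of half-life with signal recognition particle RNA, and of the gradient in other operons were chosen only after the results were seen.

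Several groups not described so far split after 5 min of rifampicin in KAE55 (edgeR's quasi-likelihood test, changes relative to the typical transcript). In late motility genes under SigD 7 of 21 rose and 10 fell, with hag (flagellin) at 2.60 ± 0.31, motA (flagellar motor) at -2.72 ± 0.24 and flgM (anti-sigma factor) at -2.10 ± 0.24. In the SOS response 2 of 9 rose and 6 fell, with dinB at 2.41 ± 0.28 and ruvA (Holliday junction helicase) at -4.34 ± 0.37. In competence 5 of 18 rose and 8 fell, with comEC, the DNA uptake channel, at -3.51 ± 0.37. Among RNA decay enzymes 3 of 11 rose and 5 fell, with the helicase gene cshA at -2.51 ± 0.17 and rph at 1.70 ± 0.14, which turned to -0.14 on the stable RNA scale. In the purine branch and salvage list 3 of 14 rose and 5 fell, with adk (adenylate kinase) at 2.14 ± 0.15 and the nucleoside transporter gene nupG at -2.57 ± 0.14. These counts were the same adjusted over the list alone, and on the stable RNA scale hag (0.72), dinB (0.58) and adk (0.31) no longer passed. On that scale the lists did not split, as 0 genes rose in each. There 14 late motility, 7 SOS, 10 competence, 8 RNA decay and 12 purine branch and salvage genes fell. The list medians there were -2.13, -3.39, -2.26, -2.18 and -2.09 in that order. Camera called none of these lists (adjusted p from 0.307 to 0.812).

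In the skin element 2 of 26 genes rose and 12 fell in KAE55 after 5 min, and 2 rose and 15 fell in KAE213. In the conjugative element ICEBs1 1 of 17 rose and 8 fell, and in KAE213 0 rose and 9 fell. On the stable RNA scale with all libraries 0 genes of either element rose in either strain. There 19 skin and 12 ICEBs1 genes fell in KAE55, and 26 and 16 in KAE213. Many of the skin and ICEBs1 genes had few counts, so no fold is given. Of the 30 rRNA rows, which the kit depletes and whose copies share reads, 24 rose in KAE55 and 29 in KAE213 after 5 min, relative to the typical transcript.

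The gradient along operons after rifampicin may come from RNA polymerases already past the promoter that finish their transcripts. The lowest Spearman correlation of position and 2 min change in the fla/che operon was 0.834 over the 4 cultures. Abundance and coding length as the source are argued against, since the lowest partial correlation was 0.485. A property of the fla/che operon alone is argued against too, since the lowest correlation was 0.986 in the pur operon and 0.952 in the pyr operon. It was 0.741 over the PBSX genes from xkdB to xlyA, which need not share 1 transcript. At 5 min the fla/che range was 0.973 to 0.991. If run-off is the source, apparent half-lives of genes far from a promoter are too long, which bears on the half-life values of both strains.

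The median apparent half-life was shorter in both KAE213 cultures than in both KAE55 cultures, and none of the 3 explanations tested could be excluded. A low stable RNA share at 0 min in 1 KAE213 library as the source stays open: with the 2 and 5 min libraries alone the difference was -1.32 min, but a KAE213 culture (3.05 min) then lay above a KAE55 culture (3.03 min). Leaving out that library's culture kept most of the difference (-0.809 of -0.902 min), with the remaining KAE213 culture at 1.64 min against 2.00 and 2.90 min in KAE55, a gap smaller than that between the KAE55 cultures. Uneven recovery of tmRNA, whose share at 5 min was 2.30% in KAE213 replicate 1 and at most 1.25% in the other cultures, stays open as well, as the difference was -0.629 min with RNase P RNA alone, with nearest cultures (1.83 and 1.93 min) closer than the spread within a strain, and with signal recognition particle RNA alone (-0.681 min) KAE213 replicate 1 (2.00 min) lay above KAE55 replicate 1 (1.90 min). An effect of the nahA allele on mRNA stability stays open: both KAE213 cultures lay below both KAE55 cultures, but the gap between the nearest, 0.360 min, was smaller than the SD of 0.637 min within KAE55.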
